A study of Caenorhabditis elegans with 6 samples.

How the data were processed

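The libraries were made from whole-worm RNA, extracted with TRIzol and prepared with the TruSeq RNA v2 kit, per the labels' protocols. The submitters' processing notes name STAR, HTSeq 0.5.4, DESeq 1.10.1 and the genome build WBcel235, with no role or order. The values analysed are the FPKM values the authors deposited, 1 per gene and library, in a table that also gives each gene's position, length, name and description. FPKM divides reads by gene length and by library depth, so it allows a gene to be compared between libraries but keeps no raw depth. A change in a few abundant genes can move the scale of a whole library. The table holds 46950 rows, of which 44017 have an identifier in the reference gene names used here. A blank name or one stored as a date was replaced through the gene identifier where possible, which filled 16 names. There were 11 names stored as dates.

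Depth was recovered from the values themselves. FPKM multiplied by gene length is a whole multiple of 1 step in each library, and the step gives the number of counted reads. With a tolerance of 0.05 reads, 88.8% of the values above 0 came out whole, and all values were whole for 89.1% of genes. The recovered depth was 19079441 to 21977419 reads per library. Because over 10% of the values were not whole, the recovered reads served only as an alternative and for checks of depth.

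The main test was limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2(FPKM + 1), with the treatment group as the only term. Genes with at least 1 FPKM in at least 3 of the 6 libraries were kept, which left 12174 of the 20845 genes with any value, 11679 of them protein-coding. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes kept, and a gene was called at an adjusted p under 0.05. A fold change on this scale understates the change of genes with low FPKM. The table holds no counts, so the tests for counts that were planned in case it did were not run. An exact permutation test of 3 libraries against 3 cannot go below p = 0.1, so none is given for single genes.

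Before the data were examined, 40 gene lists, the tests, the alternatives and the rule for naming genes were fixed. Lists were tested with camera (limma) with a preset correlation between genes of 0.01, adjusted over the 40 lists. The same test with an estimated correlation and fry, also from limma, were run as alternatives. Camera asks whether a list moved relative to all other genes, and fry whether its genes moved on balance in 1 direction. A list score is the mean over members of log2(FPKM + 1) after subtracting each member's mean over the 6 libraries. The rule named the genes with the largest changes among those called. As none was called, it named the 5 genes in each direction with the smallest unadjusted p, with no overlap between the groups and a mean of at least 5 FPKM in the higher group. It also named up to 3 genes with the smallest p in each stress, immune or neural list and in each other list past the threshold, of which the text gives some. Adjustment over a list alone covers only the members of that list, with no correction over the 40 lists. It passed 8 genes in 7 lists, none of which passed over all genes.

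The alternatives were a pseudocount of 0.1 or 5, no filter or a filter of 5 FPKM, other scalings of the libraries, quantile normalization, limma without the trend or with robust moderation, library weights, the replicate number as a block, leaving out each library in turn, a minimum log2 fold change of 1 and an adjusted p under 0.1. A further 4 settings were added after seeing the data: voom on recovered reads for genes with at least 10 reads in at least 3 libraries, voom with library weights, the score of the moulting list as a covariate, and removal of a length trend from each library. A further 4 gene lists were also added after seeing the data.

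The scripts were tested on simulated data before use. In simulated reads for the THz against Control comparison, with 11944 genes kept, 20% of the genes changed by 0.5 on the log2 scale were called, 42.9% of those changed by 1 and 77.0% of those changed by 2, with 3 false calls. When the same changes were put on the real THz values of 12174 genes, 9.0%, 41.8% and 77.3% were called. A further 5 calls fell on genes given no change, but whether THz changed these genes is not known. All 3 lists shifted by 0.3 in the simulated reads were called, with 0 other lists. The simulated genes varied independently of each other, so this does not measure false calls in lists whose genes vary together. In the real libraries the estimated correlation between genes of a list ran from -0.16 for vitellogenins to 0.97 for mitochondrially encoded genes. Figures were drawn with matplotlib 3.10.9. Positions are those in the deposited table.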

Results

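Whole worms of the nematode Caenorhabditis elegans were profiled by sequencing of polyadenylated RNA in 6 libraries, 3 from worms treated with terahertz radiation and 3 from control worms. Terahertz radiation is the band of the spectrum between microwaves and infrared light, and the series title gives a frequency of 0.26 THz. The title names genes of the immune and nervous systems as the subject, so lists of such genes were fixed beforehand, with lists for stress responses, tissues, the cuticle and metabolism. The power density, the length of exposure, the temperature and the stage of the worms are not given in the sources used here. Nothing in the labels says that the 3 libraries of a group came from separate cultures. The p-values of single genes therefore measure only the spread between these libraries, which may be technical. Camera with the preset correlation measures spread over genes, so its p-values can be very small however few the libraries are. The control libraries held 20308270, 21054408 and 21977419 counted reads, and the THz libraries held 19079441, 19440393 and 20789499. Between 17368 and 17990 genes had a value above 0 in a library.

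The 3 THz libraries resembled each other more than the 3 control libraries did. Pearson correlations of log2(FPKM + 1) lay between 0.989 and 0.992 among the THz libraries, and between 0.946 and 0.984 among the control libraries. The lowest value was between Control 2 and Control 3, which differed by more than 1 on the log2 scale at 1519 genes. Their moulting and cuticle formation genes, which build and shed the larval cuticle, had mean scores of -0.75 in Control 2 and 0.81 in Control 3, against -0.34, 0.08 and -0.14 in the THz libraries. Lysozyme genes, whose products break bacterial cell walls, scored -1.02 in Control 2 and 0.60 in Control 3. Sperm genes scored 0.53 and -0.80, and mitochondrially encoded genes scored 1.06 and -0.40, in the same 2 libraries. The first principal component held 53.3% of the variance and separated these 2 control libraries, while the second held 18.8% and separated all 3 THz libraries from all 3 control libraries. No 2 libraries agreed within sampling noise, since the chi-square of their reads per degree of freedom was at least 4.55.

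**Figure D1:**
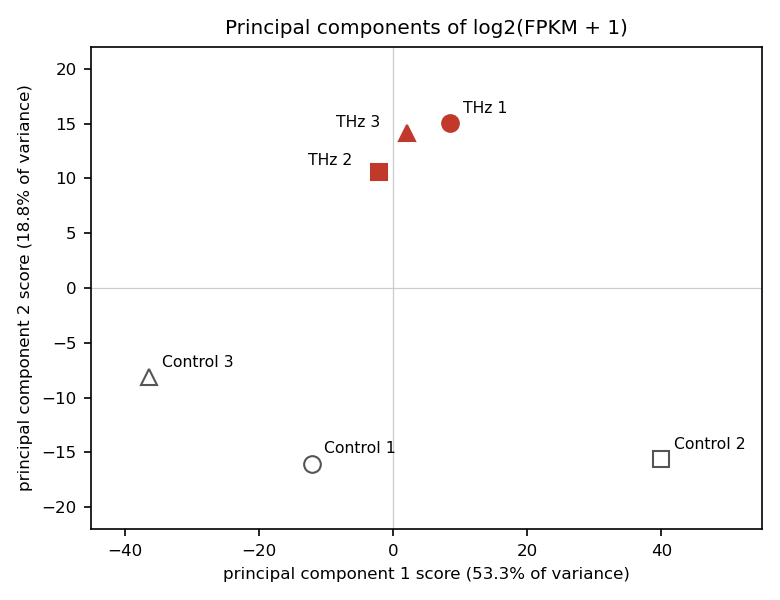
Each point is a library at its scores on the first (horizontal axis, 53.3% of the variance) and second (vertical axis, 18.8%) principal component of log2(FPKM + 1), with open symbols for Control and filled symbols for THz. Control 2 lies at 40 and Control 3 at -36.3 on the first component, and the THz libraries lie between 10.6 and 15.04 on the second, above all control libraries.

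The comparison of THz with control worms asks which genes, immune and nervous system genes among them, differ after the exposure. No single gene passed the threshold. Several gene lists shifted by small amounts on average, and camera called them with the preset correlation but not with an estimated one. Muscle genes fell by 0.32 on the log2 scale on average, with all 26 measured members lower after THz (camera adjusted p = 1.57e-11; adjusted p = 0.366 with an estimated correlation). Genes of synaptic transmission fell by 0.27, with 32 of 37 lower (adjusted p = 9.04e-08; adjusted p = 0.462 with an estimated correlation). Subunits of the proteasome, the complex that degrades tagged proteins, rose by 0.13, with all 33 higher (adjusted p = 8.93e-10; adjusted p = 0.355 with an estimated correlation). Of the 40 lists, 18 passed the threshold with the preset correlation, 14 of them lower and 4 higher after THz. None passed with an estimated correlation, where the smallest adjusted p was 0.35. Every other split of the same 6 libraries also gave lists past the threshold with the preset correlation, from 7 to 15.

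Of 12174 genes tested with limma, 0 had an adjusted p under 0.05, and the smallest was 0.269, for the troponin gene tni-1. At an unadjusted p under 0.05 there were 714 genes, 226 higher and 488 lower after THz, where chance alone gives 609. That is 68.3% lower, against 50.6% after quantile normalization. Leaving out each library in turn gave between 289 such genes (without THz 3) and 2148 (without Control 2). The share lower then ran from 46.3% without Control 3 to 86.5% without THz 2. The test on recovered reads with voom also called 0 genes, with 774 at an unadjusted p under 0.05. All 3 THz libraries lay above all 3 control libraries at 784 genes and below them at 892, together 13.8% of the genes where chance gives 10% on average. Genes can vary together, so this excess cannot be weighed. The fold changes were small, with a 5th percentile of -0.48, a median of 0.00 and a 95th percentile of 0.25 on the log2 scale. Without Control 2 limma called 234 genes, 11 higher and 223 lower. With weights estimated for each library it called 3092, 1673 higher and 1419 lower.

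Among genes whose 3 THz libraries all lay below the 3 control libraries, the smallest unadjusted p belonged to tni-1, which encodes a troponin I of muscle, the inhibitory subunit of the troponin complex. Its mean was 31.2 ± 0.638 FPKM in control and 16.8 ± 0.732 FPKM in THz worms (SD, n = 3 each), a log2 difference of -0.85 ± 0.09 (SE). It lies on chromosome X of build WBcel235, from 11375887 to 11377470. The cuticle collagen gene ram-2 (chromosome II, 11015588 to 11016881) measured 27.2 ± 5.11 FPKM against 10.6 ± 1.27 FPKM, a log2 difference of -1.28 with an adjusted p of 0.372. The glutamine synthetase gene gln-3 (chromosome IV, 16167785 to 16170859) measured 193 ± 19.1 FPKM against 120.1 ± 3.29 FPKM, a log2 difference of -0.67. The uncharacterized genes F08G2.5 (chromosome II, 13832870 to 13833653) and F28F5.6 (chromosome III, 6817316 to 6819372) measured 5.80 ± 0.409 against 2.16 ± 0.276 FPKM and 11.3 ± 0.254 against 5.75 ± 0.523 FPKM. None of these 5 genes passed the threshold over all genes with the 6 libraries. Without Control 2 all 5 passed (adjusted p = 0.00821 for tni-1, 0.00563 for ram-2, 0.0146 for gln-3, 0.0232 for F08G2.5 and 0.0365 for F28F5.6), and all 5 passed with the moulting covariate or with library weights.

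Among genes with all 3 THz libraries above the control libraries, R03D7.2 (chromosome II, 10932741 to 10935140), which encodes a protein with an AAA_12 domain, measured 26.3 ± 2.74 FPKM in control and 39.4 ± 0.956 FPKM in THz worms (SD, n = 3 each), a log2 difference of 0.57. The uncharacterized gene D1086.10 (chromosome V, 14082753 to 14083584) measured 69.97 ± 2.48 FPKM against 92.7 ± 7.36 FPKM, and the pseudogene WBGene00014955 (chromosome V, 16929167 to 16930063) 62.1 ± 2.44 FPKM against 78.6 ± 3.43 FPKM. The gene erh-2, a homolog of enhancer of rudimentary (chromosome III, 4593176 to 4593832), measured 66.3 ± 3.45 FPKM against 84.3 ± 2.59 FPKM. Its locus overlaps apc-11, and reads of overlapping genes cannot be told apart with a kit that keeps no strand. The proteasome beta subunit gene pbs-7 (chromosome I, 8695205 to 8696376) measured 183 ± 17.5 FPKM against 239.9 ± 10.1 FPKM. All 5 had an adjusted p of 0.612 and did not pass with the 6 libraries. Without Control 2 the adjusted p was 0.0147 for R03D7.2, 0.0459 for D1086.10 and 0.0380 for pbs-7, and all 5 passed with library weights.

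**Figure D2:**
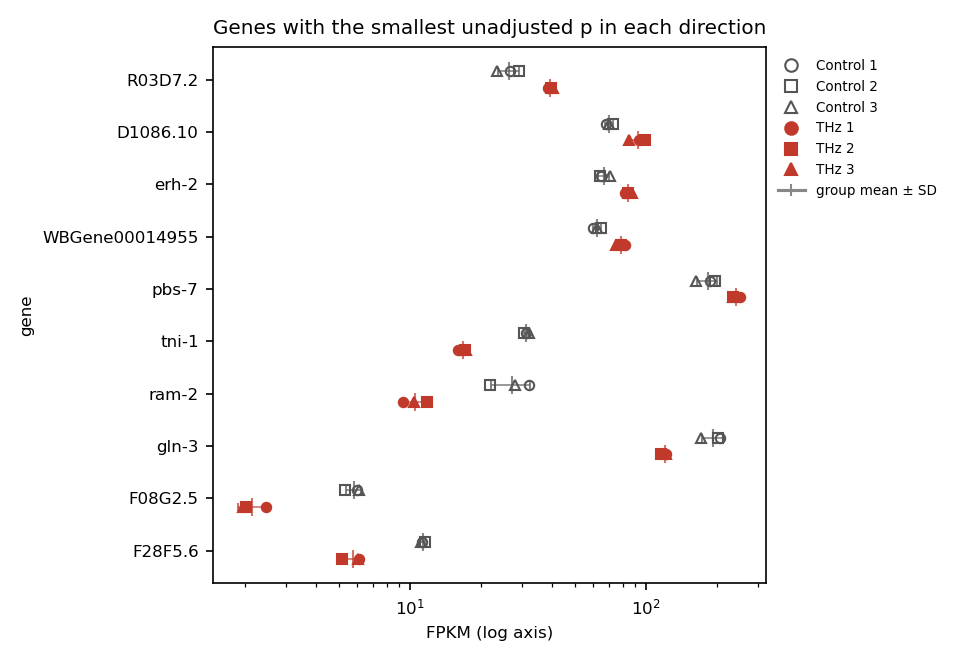
FPKM (horizontal log axis) of the 5 genes with the smallest unadjusted p in each direction among those with no overlap between the groups (vertical axis), with a symbol for each library and a bar for the group mean ± SD. All 3 THz libraries lie above the control libraries for the upper 5 genes and below them for the lower 5, and none of the 10 passed the threshold over all genes.

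Of the 7 lists of nervous system genes, 6 were lower after THz with the preset correlation and 0 passed with an estimated correlation. In the synaptic transmission list, 12 of the 37 members had all 3 THz libraries below the control libraries and none passed the test, over all genes or adjusted over the list alone. The carboxypeptidase gene egl-21, which processes neuropeptides, measured 39.9 ± 0.531 FPKM in control and 32.04 ± 0.713 FPKM in THz worms, and the GABA transporter gene snf-11 measured 2.401 ± 0.239 and 1.01 ± 0.133 FPKM (SD, n = 3). Neuropeptide genes outside the FMRFamide-like family fell by 0.19 on average, with 43 of 52 lower (adjusted p = 0.000168; adjusted p = 0.355 with an estimated correlation). Among these, nlp-55 measured 8.37 ± 1.404 FPKM in control and 4.32 ± 0.346 FPKM in THz worms, and nlp-12 measured 11.7 ± 2.04 and 7.05 ± 0.498 FPKM. The mean of that list was -0.10 after quantile normalization and -0.11 with a pseudocount of 5. Genes of thermal and touch sensing fell by 0.27, with 11 of 14 lower (adjusted p = 0.00108; adjusted p = 0.355 with an estimated correlation). The tubulin gene mec-12, needed in touch receptor neurons, was the 1 member past the threshold when adjusted over the list alone, at 16.479 ± 1.09 FPKM in control and 9.34 ± 1.04 FPKM in THz worms, but 0 members passed over all genes. Without Control 2 mec-12 passed over all genes (adjusted p = 0.0461), and nlp-55 passed with the moulting covariate (0.0490). With a pseudocount of 5 the synaptic mean was -0.15 and the thermal and touch mean -0.16, while a filter of 5 FPKM gave a synaptic mean of -0.17 and no filter a thermal and touch mean of -0.16. The mec-7 tubulin gene, whose locus overlaps deg-1, measured 10.1 ± 0.371 and 6.78 ± 0.871 FPKM.

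FMRFamide-like neuropeptide genes fell by 0.14, with 20 of 30 lower (adjusted p = 0.00952; adjusted p = 0.366 with an estimated correlation). Without Control 2 the adjusted p was 0.119, and without THz 1 it was 0.0618. After quantile normalization the mean was -0.02 (adjusted p = 0.210). The call also ended with the length trend removed (mean -0.11, adjusted p = 0.0518) and with voom and library weights (mean -0.16, adjusted p = 0.0549). Insulin-like peptide genes fell by 0.25, with 12 of 14 lower (adjusted p = 0.0255; adjusted p = 0.355 with an estimated correlation), and the call ended without Control 1 (adjusted p = 0.215) or Control 3 (adjusted p = 0.0517). Their mean was -0.04 with a filter of 5 FPKM (adjusted p = 0.575), -0.10 with no filter (0.145) and -0.15 after quantile normalization (0.112). The call also ended with voom (mean -0.19, adjusted p = 0.148), the moulting covariate (mean -0.20, adjusted p = 0.198) and the length trend removed (mean -0.22, adjusted p = 0.0519). The mean was -0.12 with a pseudocount of 5, -0.40 with library weights and -0.45 with voom and library weights. Neurotransmitter receptor genes fell by 0.13, with 23 of 29 lower (adjusted p = 0.0324; adjusted p = 0.722 with an estimated correlation). That call ended without Control 2 (adjusted p = 0.337), Control 3 (0.110), THz 1 (0.0932) or THz 3 (0.0712), and with the replicate block. After quantile normalization the mean was -0.04 (adjusted p = 0.275) and with library weights -0.07 (0.262). A filter of 5 FPKM gave -0.21 (0.0719). The call also ended with the moulting covariate (mean -0.13, adjusted p = 0.0974) and with voom and library weights (mean -0.18, adjusted p = 0.0794). The mean was -0.06 with a pseudocount of 5 and -0.25 with voom. The GABA receptor gene unc-49 measured 10.3 ± 0.655 FPKM in control and 7.36 ± 0.566 FPKM in THz worms (SD, n = 3). No member of these 3 lists passed the gene test, over all genes or adjusted over the list alone. Markers of neurons and glia in general did not pass, with 10 of 16 lower (adjusted p = 0.699).

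Antimicrobial peptide genes fell by 0.19, with 23 of 32 lower (adjusted p = 0.00952; adjusted p = 0.614 with an estimated correlation). Their score was -0.32 in Control 2 and 0.40 in Control 1, and the call ended without Control 1 (mean log2 difference -0.03, adjusted p = 0.784) or THz 2 (adjusted p = 0.184). Without Control 2 their mean log2 difference was -0.39, with library weights -0.44 and with voom and library weights -0.46. The call also ended with the moulting covariate (mean -0.09, adjusted p = 0.198) and with voom (0.0695). The saposin-like gene spp-22 measured 7.23 ± 1.69 FPKM in control and 4.55 ± 0.642 FPKM in THz worms (SD, n = 3). Immune signalling genes fell by 0.12, with 26 of 33 lower (adjusted p = 0.0263; adjusted p = 0.824 with an estimated correlation). That call ended without Control 3 (mean log2 difference -0.02, adjusted p = 0.776), THz 1 (0.0716) or THz 3 (0.117). The mean was -0.20 without Control 2 and -0.08 with a pseudocount of 5. After quantile normalization it was -0.06 (adjusted p = 0.0961) and with the moulting covariate -0.06 (0.403). The call also ended with no filter (0.0693), library weights (0.0595) and voom with library weights (0.0527). The infection response list did not pass (adjusted p = 0.127). Its member sysm-1 passed when adjusted over the list alone, at 35.4 ± 2.84 FPKM in control and 25.2 ± 0.614 FPKM in THz worms, but not over all genes. Lysozymes (adjusted p = 0.635), C-type lectins (0.933), which are carbohydrate-binding proteins, and genes of the intracellular pathogen response (0.159) did not pass. Without Control 2 the lysozyme mean went from -0.01 to -0.52 (adjusted p = 0.000162; adjusted p = 0.521 with an estimated correlation). Control 2 scored -1.02 on lysozymes, below the THz libraries (-0.22 to 0.16). Apart from sysm-1, no member of the 6 immune lists passed the gene test, over all genes or adjusted over the list alone. Without Control 2, 10 members passed over all genes, all lower after THz than in Control 1 and Control 3. Among them were the saposin-like gene spp-2 (adjusted p = 0.00563), the lysozyme gene ilys-3 (0.00596) and sysm-1 (0.0438). Control 2 itself measured 8.40 FPKM for spp-2 and 0 for ilys-3, below the THz libraries (34.7 to 40.6 and 0.797 to 1.16 FPKM). For sysm-1 it measured 33.8 FPKM, above the THz libraries (24.7 to 25.9 FPKM).

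Among the stress lists, hypoxia response genes fell by 0.17, with 9 of 12 lower (adjusted p = 0.0219; adjusted p = 0.477 with an estimated correlation). The prolyl 4-hydroxylase gene phy-2, whose enzyme modifies collagen, measured 13.99 ± 1.05 FPKM in control and 8.03 ± 0.911 FPKM in THz worms (SD, n = 3), and passed when adjusted over the list alone. The hypoxia call ended without Control 1 (adjusted p = 0.0554) or Control 3 (0.123), with the moulting covariate (0.0974) and after quantile normalization (mean -0.08, adjusted p = 0.0939). Metal response genes fell by 0.28, with 7 of 11 lower (adjusted p = 0.0263; adjusted p = 0.355 with an estimated correlation), and this was the 1 list past the threshold with fry (adjusted p = 0.0277). Both ferritin genes, which encode iron storage proteins, passed when adjusted over the list alone. The ftn-1 gene measured 4.78 ± 0.671 and 1.62 ± 0.815 FPKM, and ftn-2 measured 242 ± 34.3 and 174 ± 8.46 FPKM, in control and THz worms. Over all genes phy-2 passed without Control 2 (adjusted p = 0.0434) and ftn-2 with the moulting covariate (0.0445). The metal call ended without Control 1 (adjusted p = 0.0782) or THz 2 (0.0677), with no filter (0.0660), after quantile normalization (0.106), with voom (0.0510), with the moulting covariate (0.0588), and with voom and library weights (mean -0.43, adjusted p = 0.0527). Genes of DNA damage repair and apoptosis rose by 0.10, with 21 of 25 higher (adjusted p = 0.000568; adjusted p = 0.532 with an estimated correlation). Without Control 1 their mean log2 difference was 0.05, with library weights 0.17 and with voom and library weights 0.16. The DNA polymerase gene polh-1 measured 50.4 ± 2.96 FPKM in control and 57.9 ± 2.13 FPKM in THz worms.

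Heat shock genes did not pass (adjusted p = 0.954), with 12 of 20 higher and 8 lower. The small heat shock gene hsp-16.2, a common reporter of heat and other stress, measured 12.9 ± 6.66 FPKM in control and 6.12 ± 1.39 FPKM in THz worms (SD, n = 3), and its near-identical relatives can share reads with it. Lists of endoplasmic reticulum folding (adjusted p = 0.954), the mitochondrial stress response (0.826), antioxidant genes (0.872) and osmotic stress (0.263) did not pass. No gene of these 5 lists passed the gene test, over all genes or adjusted over the list alone. With the moulting covariate hsp-16.2 (log2 difference -1.11, adjusted p = 0.0215) and hsp-16.41 (-0.90, adjusted p = 0.0490) passed over all genes.

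In the muscle list, 9 of 26 members had all 3 THz libraries below the control libraries, and tni-1 passed when adjusted over the list alone. The myosin heavy chain gene myo-3 measured 26.9 ± 2.85 FPKM in control and 20.3 ± 1.44 FPKM in THz worms, and unc-52, which encodes the basement membrane protein perlecan, measured 34.3 ± 1.19 and 26.2 ± 2.95 FPKM (SD, n = 3). Their loci overlap K12F2.3 and hhat-1, which can share their reads. Muscle scores per library were 0.19, 0.36 and -0.07 in control and -0.27, -0.07 and -0.15 in THz worms, so Control 3 and THz 2 had the same score to 2 decimals. Pharynx genes fell by 0.51, with all 17 lower in group mean (adjusted p = 2.52e-05; adjusted p = 0.355 with an estimated correlation). Only 1 of the 17 had all 3 THz libraries below the control libraries. Pharynx scores were 0.43, -0.29 and 0.63 in control and -0.44, -0.11 and -0.21 in THz worms, so Control 2 lay below THz 2 and THz 3. The mean log2 difference of this list was -0.78 without Control 2, the control library with the lowest pharynx score, and -0.33 without Control 3. It was -0.26 with a filter of 5 FPKM and -0.88 with voom and library weights. The troponin T gene tnt-4 measured 50.3 ± 5.61 and 35.7 ± 2.18 FPKM and was the 1 member past the threshold adjusted over the list alone, and it passed over all genes without Control 2 (adjusted p = 0.0356). Oocyte and early embryo genes rose by 0.12, with 27 of 29 higher (adjusted p = 5.91e-08; adjusted p = 0.355 with an estimated correlation). Here oma-2, an oocyte maturation factor, measured 613 ± 25.1 FPKM in control and 703.1 ± 13.9 FPKM in THz worms. Germline genes rose by 0.12, with 29 of 32 higher (adjusted p = 4.01e-07; adjusted p = 0.355 with an estimated correlation). The Argonaute gene csr-1 measured 108.8 ± 8.69 and 129.7 ± 1.06 FPKM, and the helicase gene glh-2 measured 66.0 ± 4.44 and 78.5 ± 3.08 FPKM. Intestine markers (adjusted p = 0.694), vitellogenins (0.868), which are yolk proteins, and sperm genes (0.711) did not pass. Without Control 2 the mean of sperm genes went from 0.03 to 0.30 (adjusted p = 0.000533; adjusted p = 0.725 with an estimated correlation). Control 2 scored 0.53 on them, above the THz libraries (-0.21 to 0.20).

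**Figure D3:**
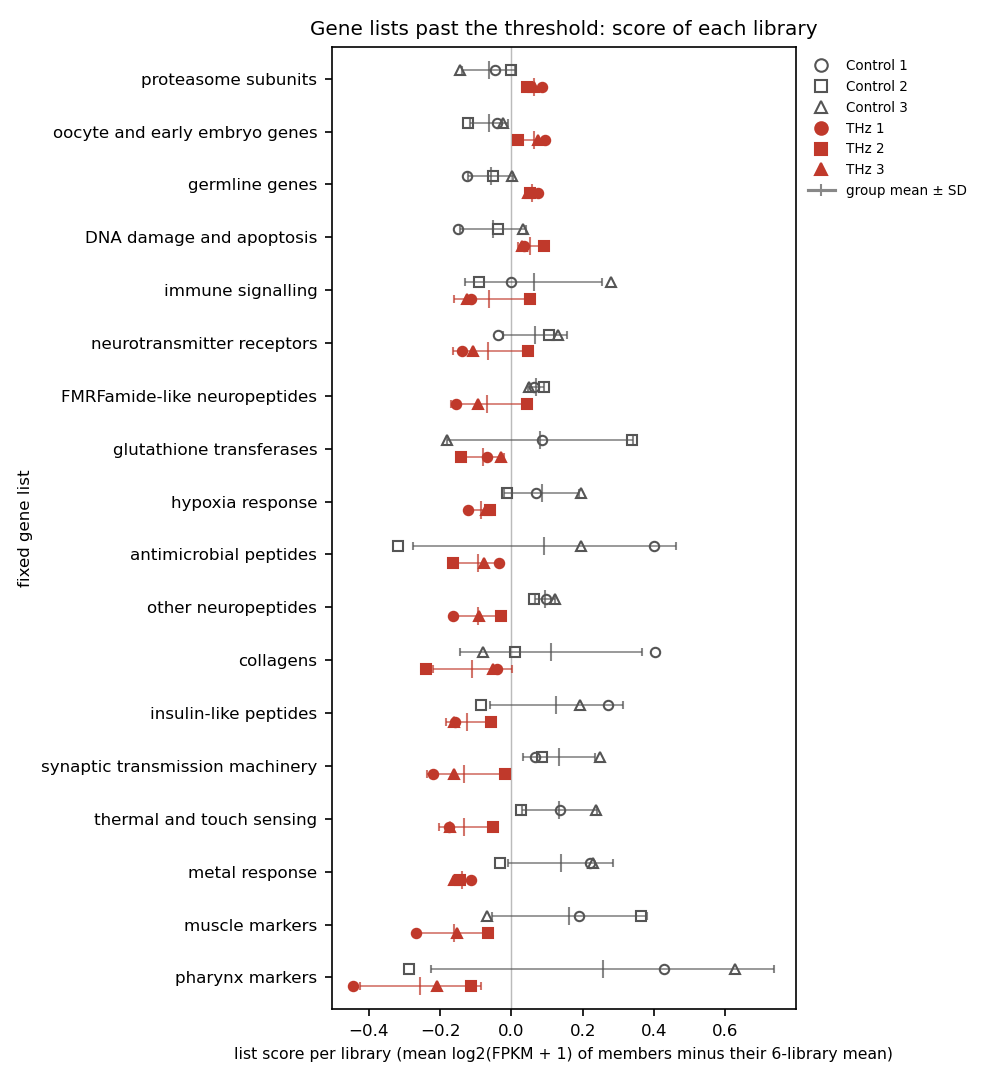
Score of each library (horizontal axis, mean log2(FPKM + 1) of a list's members after subtracting each member's mean over the 6 libraries) for the 18 lists past the threshold with the preset correlation (vertical axis), with bars for the group mean ± SD. All 3 THz libraries lie apart from all 3 control libraries for 9 of the 18 lists, and the groups overlap for the other 9.

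Of all 40 lists, 11 had scores with no overlap between the groups, 3 higher and 8 lower after THz, where chance gives about 4 on average. Lists can move together in the same 6 libraries, and this count was not made for other splits, so the excess cannot be weighed. Cuticle collagen genes fell by 0.22, with 85 of 107 lower (adjusted p = 0.00952; adjusted p = 0.532 with an estimated correlation). The collagen gene rol-8 measured 3.79 ± 0.453 FPKM in control and 1.92 ± 0.586 FPKM in THz worms (SD, n = 3). Their score was 0.40 in Control 1, 0.01 in Control 2 and -0.08 in Control 3, and the call ended without Control 1 (mean log2 difference -0.07, adjusted p = 0.784) or THz 2 (adjusted p = 0.492), and with voom (0.0636). The mean was -0.44 with library weights and -0.43 with voom and library weights. Moulting and cuticle formation genes did not pass with the 6 libraries (mean log2 difference -0.27, adjusted p = 0.123). Without Control 2 their mean was -0.71 (adjusted p = 1.63e-09; adjusted p = 0.565 with an estimated correlation). Control 2 scored -0.75 on this list, below the THz libraries (-0.34 to 0.08).

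In the proteasome list, 12 of 33 members had all 3 THz libraries above the control libraries. The regulatory subunit genes rpt-5 and rpn-1 measured 179 ± 9.72 and 120.6 ± 2.92 FPKM in control and 203.7 ± 3.16 and 135 ± 0.851 FPKM in THz worms (SD, n = 3). Glutathione transferase genes, whose products detoxify reactive compounds, fell by 0.16, with 25 of 32 lower (adjusted p = 0.0328; adjusted p = 0.794 with an estimated correlation). Their score was 0.34 in Control 2, and without it the mean log2 difference was -0.03, the adjusted p was 0.847 and the test pointed the other way. Without Control 3 the mean was -0.29. That call also ended without Control 1 (adjusted p = 0.163) or THz 2 (adjusted p = 0.402), and after quantile normalization (mean -0.10, adjusted p = 0.0939). It ended too with the length trend removed (mean -0.14, adjusted p = 0.0788), with voom (mean -0.16, adjusted p = 0.148) and with voom and library weights (mean -0.11, adjusted p = 0.193). With the moulting covariate the mean was -0.24. Glucuronosyltransferases (adjusted p = 0.0866), cytochrome P450 genes (0.159), fat metabolism genes (0.279) and targets of the insulin pathway (0.0898) did not pass. Without Control 2 the insulin pathway mean went from -0.17 to -0.42 (adjusted p = 1.47e-05; adjusted p = 0.521 with an estimated correlation). Control 2 scored -0.40 on that list, below the THz libraries (-0.12 to -0.04). In the insulin pathway list, pck-1, the gene of phosphoenolpyruvate carboxykinase, passed when adjusted over the list alone and is named here after its values were seen. Ribosomal proteins (adjusted p = 0.826), nuclear genes of the respiratory chain (0.985), mitochondrially encoded genes (0.933) and histones (0.697) did not pass. Without Control 2 the mean of mitochondrially encoded genes went from 0.01 to 0.54 (adjusted p = 6.21e-06; adjusted p = 0.521 with an estimated correlation). Control 2 scored 1.06 on them, above the THz libraries (-0.13 to 0.28). In 7 lists, all short of the threshold, the mean, the median and the test differed in sign: heat shock, endoplasmic reticulum folding, mitochondrial stress, antioxidant, ribosomal, respiratory chain and mitochondrially encoded genes.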

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

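Tests with voom, the moulting covariate and the removed length trend were chosen after seeing the data. The count of 0 called genes held under the other pseudocounts, filters, scalings, moderation settings and thresholds, with the replicate block, and with voom on recovered reads. It moved with library weights to 3092 (1673 higher, 1419 lower), with voom and library weights to 56 (5 higher, 51 lower), and with the moulting covariate to 42 (11 higher, 31 lower). Leaving out each library in turn gave 0 to 234 calls, 0 to 11 higher and 0 to 223 lower, all from the fit without Control 2. The cause was not tested for the moulting covariate. On the first principal component Control 2 lay at 40, above the THz libraries (-2.13 to 8.55). Control 1 (-12.1) and Control 3 (-36.3) lay below them. The fit without Control 2 therefore cannot tell an effect of THz from this difference between the controls. Of the calls without Control 2, 225 were also made with library weights and 11 with the moulting covariate. The 18 lists past the threshold became 0 with an estimated correlation and 1 with fry, and they numbered 12 to 22 elsewhere. Their estimated correlations ran from -0.09 for metal response to 0.46 for muscle markers, against the preset 0.01. Camera with an estimated correlation also limits its degrees of freedom to those the 6 libraries leave. For other neuropeptides, insulin-like peptides and metal response the estimated correlation was 0.00697, -0.00645 and -0.0911, below the preset. Their unadjusted camera p still rose, from 2.95e-05, 0.00894 and 0.0104 to 0.0116, 0.0498 and 0.0548. A larger correlation between genes is thus not the reason for these lists. How much each contributes for the other lists was not tested. Robust moderation does not enter camera. Of the 18 lists, 9 lost their call only with the estimated correlation and fry, of 22 settings, and the other 9 kept it in 10 to 17 settings. The glutathione transferase list turned without Control 2 (mean log2 difference -0.0314, direction up; leave-outs from -0.291 to -0.0314), and 3 named genes turned: clpp-1 (-0.0326 with library weights, -0.00878 with voom and library weights), hsp-60 (-0.0476 without Control 3, the lowest of leave-outs reaching 0.268) and gst-7 (-0.0241 with library weights). The cause was not tested. Of the other results for the 89 named genes, 1731 kept direction and side of the threshold and 107 passed it. The labels state no pairing by replicate number. Deviations of same-numbered libraries correlated at -0.01, -0.14 and 0.03, and libraries did not correlate best with their own number. These values show no pairing, but so few libraries cannot exclude it. With the replicate block 0 genes were called, 532 had an unadjusted p under 0.05, and 17 lists passed. The correlation of Control 2 and Control 3 was 0.946, 0.942 as Spearman's and 0.925 with a pseudocount of 0.1, which gives more weight to low values. At the depth of 19079441 to 21977419 reads, changes of 0.5 on the log2 scale were called for 9.0% of genes when put on the real values, so small changes of single genes would mostly be missed.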

Other observations

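The tests of the somatic share, of depth and of library weights, and the counts over other splits of the libraries, except that of lists, were chosen after their results were seen, as were the 4 added lists, whose values had not been seen. Genes of the structures that attach muscle to the cuticle, such as integrin and its partners, fell by 0.29 on the log2 scale on average, with 21 of 21 lower after THz (camera adjusted p over the added lists = 2.38e-08; adjusted p = 0.132 with an estimated correlation). Among them deb-1, the gene of vinculin, measured 50.4 ± 2.28 FPKM in control and 41.3 ± 5.54 FPKM in THz worms (SD, n = 3), and the LIM domain gene unc-97 measured 29.95 ± 2.801 and 23.96 ± 2.327 FPKM. Basement membrane genes fell by 0.13, with 17 of 19 lower (adjusted p = 0.0404; adjusted p = 0.401 with an estimated correlation), and nid-1, the gene of nidogen, measured 19.5 ± 0.318 and 16.03 ± 1.05 FPKM. Genes of DNA replication and mitosis rose by 0.17, with 32 of 32 higher (adjusted p = 1.065e-11; adjusted p = 0.132 with an estimated correlation). The ribonucleotide reductase gene rnr-2 measured 350.3 ± 31.8 FPKM in control and 415 ± 12.2 FPKM in THz worms, and the kinase gene cdk-1 measured 130.6 ± 4.31 and 149.5 ± 5.23 FPKM. Patched-related and astacin genes did not pass, with 17 of 26 lower (adjusted p = 0.0791). No gene of these 4 lists passed the threshold over all genes.

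Control 2 differed from the other controls at single genes of the cuticle and the gut. Its level of the cuticlin gene cut-2 was 2.18 FPKM, against 50.2 in Control 1, 69.4 in Control 3 and 6.07 to 17.5 in the THz libraries. The gut protease gene cpr-1 measured 51.9 FPKM in Control 2, 1204 and 1811 FPKM in the other controls, and 720 to 920 FPKM in the THz libraries. Without Control 2 the called genes included 17 collagen genes, 10 moulting genes and 7 pharynx genes, all lower after THz than in Control 1 and Control 3. In the other direction, the collagen gene col-159 measured 223 FPKM in Control 2 against 109 in Control 1, 15.9 in Control 3 and 46.2 to 60.2 in the THz libraries, and col-129 measured 342 FPKM against 210.5, 34.5 and 83.0 to 145. These genes were picked for their size after their values were seen.

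The first pattern is the low level of moulting genes in Control 2, where 21 of 27 measured members were below the mean of the other 5 libraries, by 0.90 on average. Sequencing depth argues against itself as a cause, since Control 2 had 21054408 reads (21.05 after division by 1e6), inside the range of the others, and after removing the length trend the mean was still -0.86. A different phase of the moulting cycle may account for it, but patched-related and astacin genes outside the list, many of which act in moulting, had a median difference of 0.0267, against a bound of -0.5. They had an SD of 0.40, with 11 of 24 lower, and the median lay at percentile 52.6 of random lists matched on expression. These genes thus did not fall together in Control 2. Which of them cycle in these worms was not measured here, so this cannot decide on the phase. Among cuticle genes outside the moulting list, dpy-7 and sqt-3 were lower in Control 2 (4.52 and 44.4 FPKM) than in Control 1 (29.1 and 319 FPKM) and Control 3 (41.8 and 446 FPKM). The collagen genes col-159 and col-129 were higher in Control 2 than in either. No batch is given in the labels, and the reason for the difference stays open.

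The second pattern is the fall of muscle and neural lists beside the rise of germline and proteasome lists. Gene length is argued against, since the smaller of the shares kept by the muscle and synaptic shifts was 1.02 after removing the length trend. With the moulting score as a covariate the smaller share was 0.891, so these shifts mostly remained beside that score. The score was not shown to measure moulting phase, so this cannot decide on the phase of the libraries. Part of the neural fall depended on the scaling. After quantile normalization the mean was -0.02 for FMRFamide-like peptides, -0.04 for neurotransmitter receptors and -0.10 for other neuropeptides, against -0.14, -0.13 and -0.19 in the main test. The muscle, synaptic, germline and proteasome lists kept their calls in that setting. A smaller share of some somatic tissues, or more germline and embryos, could give a like pattern. RNA of whole worms cannot tell this apart from regulation within tissues. Intestine markers moved by -0.01 and markers of neurons and glia by -0.09 on average, and neither list passed. Muscle minus intestine, -0.31 after THz against control, overlapped between the groups, so it could not decide whether all somatic tissue fell alike. The added lists went with a fall of muscle genes beyond the sarcomere (2.38e-08), a fall of extracellular matrix genes (0.0404) and more dividing cells (1.065e-11), each only with the preset correlation. These remain hypotheses, since replication genes are also active in the germline, and THz treatment itself stays among the open explanations.

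The third pattern is the 3092 genes called with library weights. The weights ranged from 0.18 for Control 2 to 4.29 for Control 1. Another split of the 6 libraries, Control 1, THz 1 and THz 3 against the rest, called 2218 genes with its own weights, so the count may reflect weights estimated from too few libraries.

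With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split called 0 genes and the highest of the other splits 1, so all 10 gave at least as many, and 714 genes had an unadjusted p under 0.05 in the real split against 1166 in the highest other (4 of the 10 splits, the real one included, gave at least as many). It gave 18 lists past the threshold against 7 to 15 in the other splits, and with the moulting score as a covariate 42 genes against at most 1. Without Control 2 the 10 splits of the 5 libraries are likewise too few, with 234 genes in the real split and 1 in the highest other. In that real split both controls also lay below the THz libraries on the first principal component, where the controls differed most.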
